A study of Homo sapiens with 2 samples.

How the data were processed

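Total RNA from wild-type SK-HEP-1 cells and from SK-HEP-1 cells with EZH2 knocked down was hybridised to NimbleGen arrays in 1 colour, with Cy3 as the dye, per the labels. The labels name 1 sample per group and no cells with a control hairpin. The deposited values of each array are intensity on a linear scale after RMA (background correction, quantile normalization between arrays and a summary over the probes of a feature), per the submitters' processing notes, which name RMA without a version. The values of both arrays had nearly equal quantiles. Which arrays were normalized together and the background settings are not given in the sources used here. The other deposited column of each array file, named as an error of the expression value per the file headers, has no stated meaning and was not used. The annotation in the files gives gene names, gene IDs and coordinates on human HG18, and coordinates are printed as it gives them.

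Each array held 45033 gene features, 45031 of them summarised over 3 probes, and 1 control row over 5000 random probes, which was left out of all gene values and served as the background level. Of the gene features 42947 named a gene and 2086 named none and were left out. Gene symbols were updated through the gene ID with a table of human RefSeq genes (GRCh38.p14), of which no coordinate was used, and 38916 features (90.6%) had an ID in it. Older names were kept for the rest. The deposited series-wide value table held 28243 of the same features with intensity values equal to within a relative difference of 8.75e-07. It held all 26223 features at 100 or more on both arrays, none of the 14132 under 100 on both and 2020 of the 4678 in between, by a rule that is not stated. The values of the array files were therefore used, with the series-wide table as an alternative.

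Intensities were taken to log2 without further scaling. A feature stayed when the higher of its 2 values was at or above the 40th percentile of its array (125.5 on the wild-type array, 121.3 on the other), which left 28132 features and 16030 genes, 8509 with 1 feature and 7521 with 2 or more. Features of 1 gene were averaged on the log2 scale, and the log2 ratio is the array labelled EZH2 knockdown minus wild type. This filter keeps a gene that is dim on average only if it is bright on 1 array, so the SD of the log2 ratio was 1.96 in the lowest of 10 equal groups of mean signal, where 70.9% of genes were 2-fold different, and 0.51 in the highest group, where 5.36% were. The number of arrays limits the precision, and with 1 per group no test was run. The SD of log2 ratios between features of a gene, pooled to 0.59, was the yardstick for single genes. A value at or below the random-probe control of its array was treated as background, and the difference is then given as at least the bright value over the control or the dim value, whichever is higher.

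The 45 gene lists covered polycomb and chromatin complexes, genes reported silenced by EZH2, the cell cycle, liver, epithelial, mesenchymal and other cell types, immunity, matrix, signalling, stress and metabolism, and were written from textbook knowledge. The median log2 ratio of each list with 5 or more measured members was placed among the medians of 10000 random lists of the same size, drawn from genes in the same one of the 10 signal groups. A list stood apart below the 1st or above the 99th percentile, which describes these arrays and is no test of the conditions. The lists share members, 5 between collagens and fibroblast genes, 5 between cytokines and NF-kB targets, and 4 between mesenchymal genes and each of the collagen and fibroblast lists. Genes were named by a rule. It took the measured PRC2 subunits, the 15 highest and 15 lowest log2 ratios among genes at or above the 60th percentile on the brighter array whose features go the same way, and up to 4 members with the largest absolute ratio from each list that stood apart and from the polycomb, cell cycle, epithelial, mesenchymal, hepatocyte, endothelial and interferon lists. Uncharacterised open reading frames and genes that the annotation places on the Y chromosome are not named, and not every gene that met the rule is printed. Lists, rule, thresholds and the alternatives were chosen before the data were examined, except where a later choice is stated.

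The alternatives were centring each array on its median, a new quantile normalization, removal of a loess trend of the ratio with signal, no filter or a filter at the 60th percentile, the brightest feature per gene, the series-wide table, thresholds of 1.5-fold and 3-fold, counts of features, genes whose features all pass, random lists not matched on signal and the mean of a list. After the data were seen, a floor at the random-probe control and lists of only genes with 2 or more features were added. The calculations over single genes were tested on simulated data made from these features, with a noise SD of 0.3 per feature. That noise is smaller than the SD of 0.59 observed between features of a gene. The shares of genes past 2-fold in the simulation are therefore not error rates of these arrays. In the step over 15026 genes, all genes simulated with 4-fold changes that passed the signal filter came out past 2-fold (50 of 50 simulated genes passed for higher and 49 of 50 for lower), as did 95.9% of the 49 that passed with a log2 change of 1.5, 96.0% of 50 with -1.5 and 0.047% of unchanged genes. The step over 16030 genes used the observed ratios and lists of 30 genes drawn at random. Of 500 such lists left unchanged, 8 stood apart, and 46 of 50 lists shifted by 0.6 on the log2 scale were found. Random lists ranked among random lists rarely stand apart by construction. The share checks the calculation and gives no error rate for lists of co-regulated genes. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.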

Results

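Gene expression was measured in SK-HEP-1, an established human line from a liver tumour, with 1 array of wild-type cells and 1 array of SK-HEP-1 cells labelled as carrying a short hairpin RNA against EZH2. Each group had 1 array, so no difference given here has a replicate check, and no p-value or replicate SD is given. Both arrays carried 45033 gene features. The median intensity was 230.8 arbitrary units on the wild-type array and 228.3 on the other, and the control of random probes read 21.4 and 24.6. Of all gene features, 10.8% on the wild-type array and 13.3% on the other were at or below that control. The log2 intensities of both arrays correlated across gene features with Pearson r = 0.943, where features are not independent replicates. After the signal filter 16030 genes were measured. Where a gene had several features, the spread of their log2 ratios is given as an SD between features. Features of a gene stand for different transcript records, so that SD can hold differences between transcripts as well as technical spread. It holds no variation between cultures. Pooled over genes, that SD was 0.59 on the log2 scale.

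The design asked which transcripts differ between wild-type SK-HEP-1 cells and cells in which EZH2 was targeted. EZH2, the histone H3 lysine 27 methyltransferase of polycomb repressive complex 2 (PRC2), was close to equal on both arrays, while genes of DNA replication were higher on the array labelled EZH2 knockdown. Genes of hypoxia and glycolysis, collagens, inflammatory cytokines, antigen presentation, cholesterol synthesis and the interferon response were lower on it, and among these the calls for cytokines, MHC class II, cholesterol and interferon genes ended under some alternative settings. Genes reported to be silenced by EZH2 did not stand apart as a group. Of the 16030 measured genes, 1609 (10.0%) were 2-fold or more higher on the array labelled EZH2 knockdown, 1827 (11.4%) were 2-fold or more lower and 12594 lay within 2-fold.

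EZH2 (gene ID 2146, chromosome 7 from 148135407 to 148212347 in the HG18 annotation of the array) was measured by 1 feature of 3 probes. Which exons those probes match is not given in the sources used here. EZH2 read 1262 on the wild-type array and 1216 on the array labelled EZH2 knockdown, 96.3% of the wild-type value and a log2 ratio of -0.05. With 2 times the pooled SD between features on either side, that ratio ran from -1.23 to 1.12. That range is a rough yardstick and no error range for EZH2, because the SD is pooled over genes of all signal levels. A moderate lowering of the transcript was not excluded by this 1 feature. Because the targeted gene was not lower, the second array is called the array labelled EZH2 knockdown throughout, and every direction is relative to the wild-type array under that label. The paralogue EZH1 had a log2 ratio of -0.50 from 1 feature. The core subunits EED and SUZ12 had log2 ratios of 0.50 (SD 0.41 between 3 features) and 0.23 (SD 0.21 between 2 features). The histone-binding subunits RBBP4 and RBBP7 had 0.55 (SD 0.29 between 4 features) and 0.72 (1 feature). PHF19, an accessory subunit that reads methylated H3, was 2.53-fold higher, at 1079 and 2726 (log2 ratio 1.34, SD 0.24 between 2 features). The other accessory subunits JARID2, MTF2, PHF1 and AEBP2 had log2 ratios of 0.18, 0.29, 0.13 and 0.35, and the features of JARID2, PHF1 and AEBP2 differed in sign. The median over the 11 PRC2 genes was 0.29, at the 84.1st percentile of random lists of like signal. PRC1, the complex that ubiquitinates histone H2A, had a median of 0.41 over 19 subunits (97.4th percentile), with 3 subunits 2-fold or more higher and none lower. CBX8 and CBX6 had log2 ratios of 1.14 and 1.01. PHC3 had 1.06 with an SD of 2.37 between 3 features, and its brightest feature had -0.46. With the mean in place of the median, the PRC1 list lay at the 99.4th percentile (0.44).

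**Figure D1:**
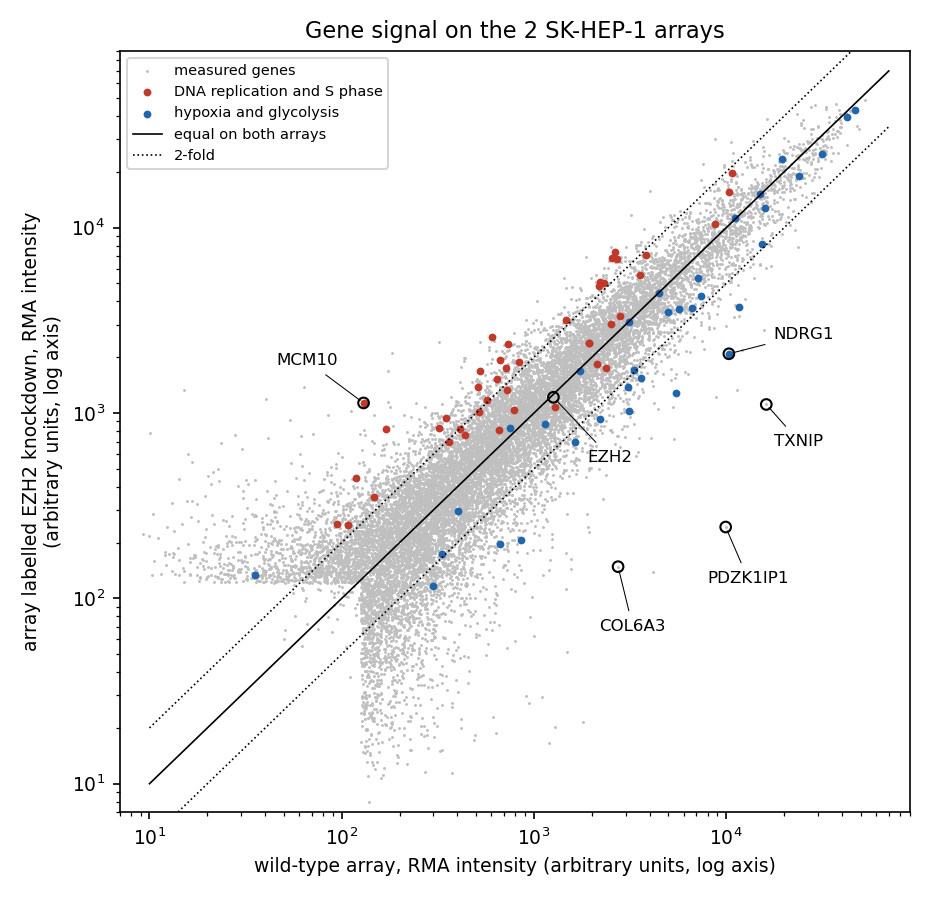
RMA intensity of each measured gene on the wild-type array (x axis) and on the array labelled EZH2 knockdown (y axis), in arbitrary units on log axes, with members of the DNA replication list in red, members of the hypoxia and glycolysis list in blue, equality as a solid line and 2-fold differences as dotted lines. EZH2 (1262 and 1216) lies on the line of equality, MCM10 (130 and 1133) lies above it, and NDRG1, TXNIP, PDZK1IP1 and COL6A3 lie below it.

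The genes of DNA replication and S phase were the only one of the 45 gene lists above the 99th percentile of random lists. Their median over 43 measured members was 2.17-fold higher (log2 ratio 1.12), where 95% of random lists of like signal lay between -0.16 and 0.28. Of the members, 24 were 2-fold or more higher, none was 2-fold lower, and 40 had a ratio above 0. MCM10, which helps to activate the replicative helicase, read 130 and 1133 (log2 ratio 3.13, SD 0.32 between 3 features), and 1 of its features was at the random-probe level on the wild-type array. The S-phase transcription factor E2F2 had a log2 ratio of 2.27 (SD 0.57 between 2 features). GINS3, a subunit of the helicase, had 2.09 (SD 0.46 between 3 features), and the G1/S cyclin CCNE2 had 1.91 (SD 0.66 between 3 features), with 1.15 at its brightest feature. Mitotic and G2/M genes did not stand apart, with a median of 0.17 over 44 members (92.3rd percentile). Among them 2 were 2-fold or more higher, the kinetochore gene SPC25 (log2 ratio 1.94) and the separase gene ESPL1 (1.17), and none was 2-fold lower. The CDK inhibitors and RB family had a median of -0.08 over 12 genes (28.9th percentile). RBL1, a pocket protein related to RB1, had 1.55 (SD 0.65 between 2 features) and the CDK inhibitor CDKN1A, also known as p21, had -0.62 (SD 0.17 between 2 features). Replication-dependent histones had a median of 0.12 (69.0th percentile).

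Of the 45 lists, 12 lay below the 1st percentile of random lists, and 0.9 lists would lie outside the 1st to 99th percentile by chance if genes varied independently, which co-regulated genes do not. Genes of hypoxia and glycolysis had a median 1.49-fold lower on the array labelled EZH2 knockdown (log2 ratio -0.57 over 34 members), where 95% of random lists lay between -0.20 and 0.25. Of these 11 were 2-fold or more lower and 1 was higher. NDRG1, a hypoxia-inducible stress gene, read 10318 and 2087 (log2 ratio -2.31, SD 0.07 between 3 features). The glucose transporter SLC2A3 had -2.09 (SD 0.21 between 2 features) and ANKRD37, a target of the hypoxia-inducible factor HIF1, had -2.04. The carbonic anhydrase CA12 had 1.91 from 1 bright feature and 0.13 when its dim features were averaged in.

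Collagens and basement membrane genes had a median 1.58-fold lower (log2 ratio -0.66 over 31 members), where 95% of random lists lay between -0.26 and 0.31, and 10 members were 2-fold or more lower. COL6A3, a chain of type VI collagen, read 2737 and 148 (log2 ratio -4.21, SD 0.56 between 2 features). COL1A1, a chain of type I collagen, had -1.83 (SD 0.91 between 2 features), and COL7A1, the collagen of anchoring fibrils, had -1.64. The laminin chain LAMA4 was the 1 member 2-fold or more higher, with 3.31 from 1 bright feature and 0.52 over all its features. Genes of fibroblasts and hepatic stellate cells (median -0.91 over 15 members, 7 lower and 1 higher, 0.1st percentile) shared 5 measured members with the collagen list. The nerve growth factor receptor NGFR was at the level of the random probes on the array labelled EZH2 knockdown, at least 5.75-fold lower, with a log2 ratio of -1.66 over all its features. Mesenchymal genes of the epithelial-mesenchymal transition had a median of -0.42 over 27 members, of which 9 were 2-fold or more lower and 1 was higher (0.19th percentile). SNAI1, a transcription factor that represses epithelial cadherin, had -2.39 from 1 feature. Epithelial genes did not stand apart, with a median of -0.26 over 26 members, 9 lower and 2 higher (4.3rd percentile). The tight junction gene TJP3 had -2.96 (SD 0.73 between 2 features), the epithelial transcription factor ELF3 had -2.47 (SD 0.58 between 2 features) and the desmosome gene DSP had -2.29. Without the signal filter the epithelial median was -0.41 (0.14th percentile), and with the mean it was -0.56 (0.23rd percentile), both below the 1st percentile of random lists.

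Chemokines and cytokines had a median 1.71-fold lower (log2 ratio -0.77 over 24 members), where 95% of random lists lay between -0.33 and 0.41, and 8 members were 2-fold or more lower and 1 higher. The granulocyte growth factor CSF3 had a log2 ratio of -2.09, the neutrophil chemokine CXCL8 had -1.69 and read 3255 and 1011, and the cytokine IL1A had -1.68, each from 1 feature. Targets of the transcription factor NF-kB, which shared 5 members with that list, had a median of -0.64 over 20 members, with 8 lower and 2 higher (0.01st percentile). The complement gene C3 had -1.81, the NF-kB cofactor BCL3 had -1.49 and the pentraxin PTX3 had 1.39. Both calls ended when only genes with 2 or more features were kept, where the medians were 0.015 for chemokines and cytokines (37.4th percentile) and 0.063 for NF-kB targets (50.2nd percentile). Antigen presentation was lower in both classes. MHC class I genes had a median of -0.49 over 20 members (0.03rd percentile), of which 2 were 2-fold or more lower and none higher. The immunoproteasome subunit PSMB9 had -1.07 (SD 0.15 between 2 features), HLA-F had -1.05 (SD 0.25 between 2 features) and HLA-C had -0.90 (SD 0.48 between 6 features). The HLA genes are near-identical in parts, so their features are not independent of each other. MHC class II genes had a median of -1.10 over 9 members, with 5 lower and 1 higher (0.255th percentile). CD74, the invariant chain that escorts class II molecules, read 1234 and 190 (log2 ratio -2.70, SD 0.58 between 4 features), and HLA-DRB1 had -1.33 (SD 0.57 between 5 features). With the brightest feature of each gene the class II list lay at the 1.61st percentile (-0.80). Type I interferon response genes had a median of -0.39 over 36 members, 4 lower and 3 higher (0.29th percentile). The RNA sensor RIGI had -2.04 and the antiviral gene IFIT3 had -1.48, while IFIT5 had 1.21 (SD 0.12 between 2 features) and the antiviral GTPase MX1 had 1.09. This call ended with the mean over members (-0.29, 2.49th percentile) and with the brightest features (-0.32, 1.1st percentile).

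**Figure D2:**
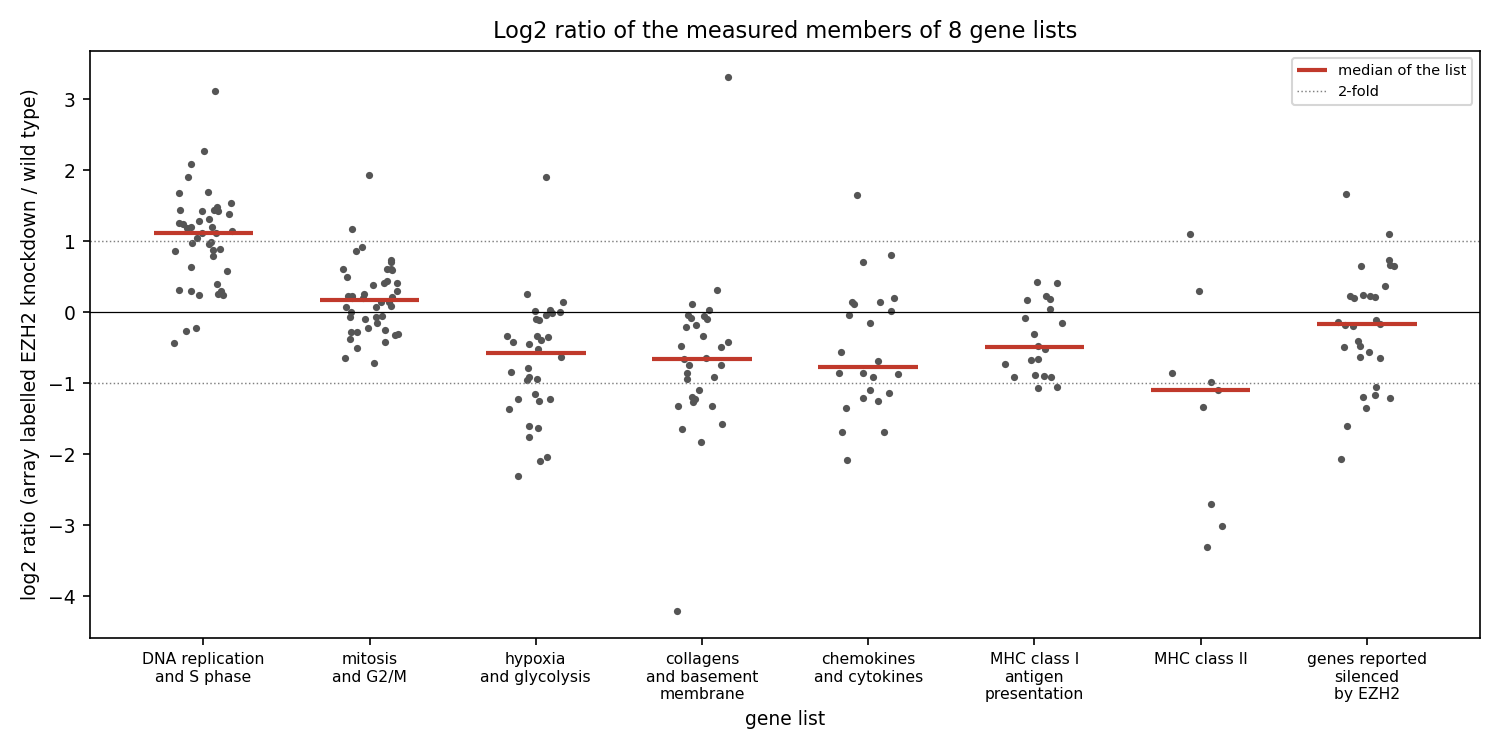
Log2 ratio of the array labelled EZH2 knockdown to the wild-type array (y axis) for each measured member (points) of 8 gene lists (x axis), with the list median as a red line and 2-fold differences as dotted lines. The DNA replication median is 1.12 while that of mitosis is 0.17, and the medians of the hypoxia, collagen, chemokine and MHC lists lie between -0.49 and -1.10.

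Cholesterol synthesis genes had a median of -0.35 over 25 members, with 3 members 2-fold or more lower and none higher (0.26th percentile). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, read 4439 and 1055 (log2 ratio -2.07, SD 0.07 between 2 features). The sterol oxidase MSMO1 had -1.59 (SD 0.76 between 3 features) and FDFT1, which makes squalene, had -1.06 (SD 0.06 between 4 features). The cholesterol list lay at the 1.02nd percentile with a stricter signal filter (-0.29). Ribosomal proteins had a median 1.15-fold lower (log2 ratio -0.20 over 61 members, 0.245th percentile). None of them reached 2-fold, and RPS3A (-0.79, SD 0.21 between 2 features) differed most. Oncofetal liver and progenitor genes had a median of -0.47 over 15 members, 4 lower and 1 higher (0.73rd percentile). The fetal growth factor IGF2 had a log2 ratio of -3.05 (SD 0.62 between 2 features) and the heparin-binding growth factor MDK had -1.52 (SD 0.07 between 4 features). That call ended without the signal filter (-0.17, 14th percentile). Against random lists not matched on signal, the cholesterol, ribosomal protein and oncofetal lists lay at the 1.85th, 1.91st and 1.95th percentiles.

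Genes reported silenced by EZH2 had a median of -0.17 over 30 measured members, of which 2 were 2-fold or more higher, 7 were lower and 21 lay within 2-fold (10.4th percentile). KLF2, an endothelial and growth-restraining transcription factor, had a log2 ratio of 1.67 (SD 0.72 between 2 features), and MYT1, a neural zinc-finger gene, had -1.35 (SD 0.55 between 2 features). Developmental transcription factors that carry polycomb marks in many cell types had a median of 0.24 over 66 measured genes, 12 higher and 5 lower (95.5th percentile). The homeobox genes BARHL1 and ISL1 read 29.0 and 178 (log2 ratio 2.62) and 41.8 and 162 (1.95), where the wild-type value of BARHL1 lay little above the control of 21.4 and leaves the size of its ratio uncertain. The endoderm and endothelial factor SOX17 was at the random-probe level on the array labelled EZH2 knockdown, at least 9.90-fold lower. The HOX genes had a median of 0.13 over 30 members, 4 higher and 5 lower (69.1st percentile), with HOXA10 at 1.49 from 2 features and HOXA2 at -1.82 from 1. DNA and histone modifying enzymes had a median of 0.21 (85.9th percentile).

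Hepatocyte genes had a median of -0.27 over 20 members, 3 of them 2-fold or more higher and 7 lower (25.2nd percentile). The antithrombin gene SERPINC1 had 2.45 from 1 bright feature (26.1 on the wild-type array, little above the control of 21.4) and 1.14 over all its features, the protease inhibitor SERPINA1 had -1.57 (SD 0.45 between 3 features) and the liver pioneer factor FOXA1 had -1.85. Endothelial genes had a median of -0.23 over 24 members, 4 of them 2-fold or more higher and 4 lower (11.3rd percentile), with the semaphorin receptor NRP2 at -2.20 (SD 0.63 between 5 features) and ESM1 at 1.89 (SD 0.17 between 2 features). Leukocyte genes (0.02, 52.8th percentile), neuronal genes (0.30, 83.1st percentile) and cancer-testis genes (-0.70 over 9 members, 8.34th percentile) did not stand apart, and neither did the reference genes (-0.02, 40.5th percentile). The signalling lists had medians of -0.39 for Wnt antagonists (4.64th percentile), -0.06 for Wnt ligands, receptors and targets (31.2nd), -0.21 for the TGF-beta pathway (5.55th), -0.18 for the Notch pathway (21.2nd) and -0.01 for ligands of NK and T cells (38.9th). Integrins and adhesion genes had a median of -0.11 (21.3rd percentile) and matrix proteases and their inhibitors had 0.06 (58.9th). The stress lists had medians of 0.20 for p53 targets (87.2nd percentile), 0.18 for apoptosis regulators (81.9th), -0.13 for the unfolded protein and amino acid response (9.11th), 0.15 for the NRF2 response (81.9th), 0.16 for immediate early genes (80.6th), 0.08 for metallothioneins (59.0th) and 0.21 for heat shock genes (91.7th). With the brightest feature of each gene the heat shock list reached 0.50 (99.97th percentile). Oxidative phosphorylation (-0.10, 7.58th percentile) and fatty acid synthesis and lipid storage (0.02, 49.3rd) completed the lists.

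**Figure D3:**
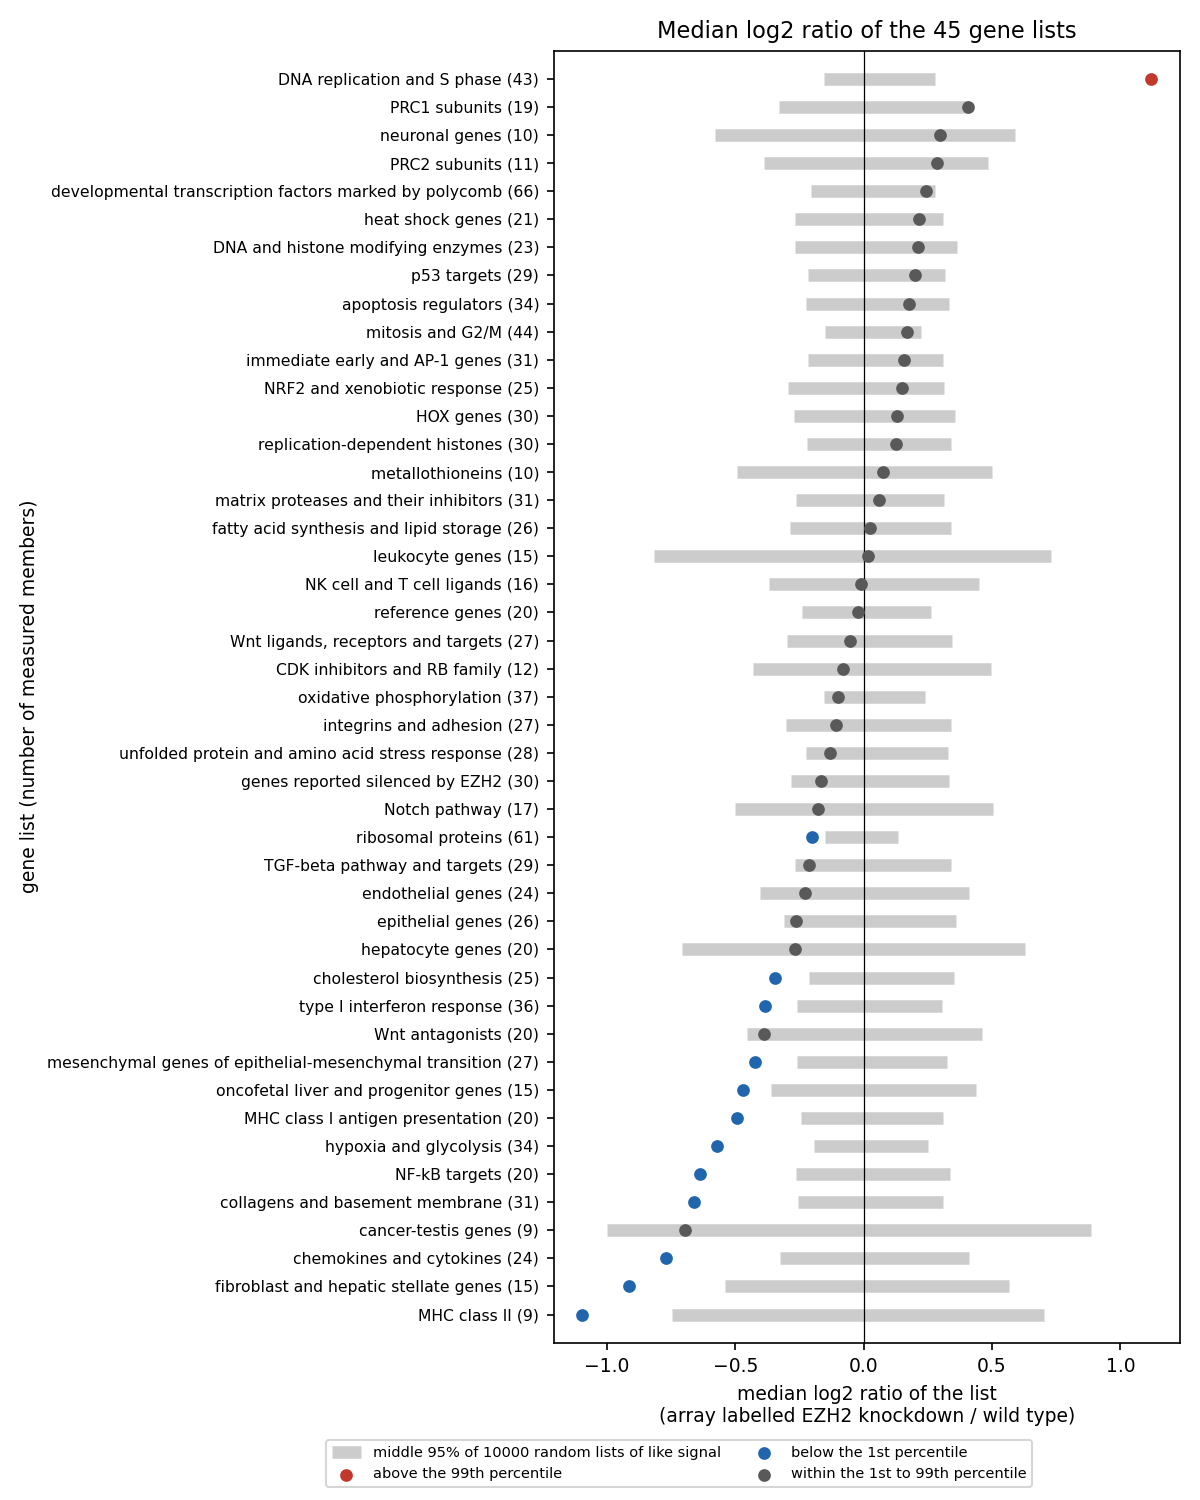
Median log2 ratio of the array labelled EZH2 knockdown to the wild-type array (x axis) for the 45 gene lists (y axis, measured members in brackets), with the range of 95% of random lists of like signal as grey bars. The DNA replication list at 1.12 is the 1 list above the 99th percentile, and 12 lists in blue are below the 1st.

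The largest single differences had few features behind them. Among genes at or above the 60th percentile on the brighter array, each of the 15 with the highest ratios passed the signal filter with 1 feature. So did 12 of the 15 with the lowest ratios, among them PPL, FYB1, DEFB130A and UGT1A10. On the dimmer array, 4 of the 15 highest and 6 of the 15 lowest were at or below the random-probe control. PDZK1IP1, a small membrane protein also known as MAP17, was 40.9-fold lower, at 9930 and 243 (log2 ratio -5.36, SD 0.10 between 2 features). TXNIP, the thioredoxin-binding protein that restrains glucose uptake, was 14.5-fold lower, at 16146 and 1112 (log2 ratio -3.86, SD 0.34 between 2 features). The desmosomal linker PPL and the adaptor FYB1 were at the random-probe level on the array labelled EZH2 knockdown, at least 20.0-fold and 19.7-fold lower. The defensin gene DEFB130A was at least 72.8-fold lower and the transferase gene UGT1A10, which shares exons with the rest of the UGT1A family, read 943 and 27.2 (log2 ratio -5.11), the dimmer value little above the control of 24.6, so that the size is uncertain. On the other side, BSND, a chloride channel subunit, read 63.9 and 1381 (log2 ratio 4.43) and ANKRD1, a stretch-responsive cofactor, read 61.5 and 747 (log2 ratio 3.60). NRROS, which tethers latent TGF-beta, read 27.8 and 764, the zinc-finger gene ZNF112 read 30.4 and 636, and SLITRK1, a neuronal membrane protein, read 22.7 and 501, so their wild-type values lay little above the random-probe control of 21.4 and the sizes of their log2 ratios (4.78, 4.39 and 4.47) are uncertain. Dim features of the same gene changed many of these values. When they were averaged in, 9 of the 15 highest and 7 of the 15 lowest genes moved by more than the SD between features, WNT8A from 4.87 to 2.40, KIF19 from -4.86 to -1.70 and DSCR8 from -4.92 to -0.98. Genes with 1 feature past the signal filter were 2-fold different more often (28.5%) than genes with 2 or more (13.4%). The ratio of the latter is a mean over features, so the shares do not compare like values.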

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

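Only the floor at the random-probe control and the restriction to genes with 2 or more features were chosen after the data were seen. No paired analysis was possible because each group had 1 array. The log2 ratio of EZH2 lay between -0.12 and -0.04 over all settings run on it. DNA replication genes stayed above the 99th percentile in all settings (median 1.04 to 1.21), and the collagen (-0.94 to -0.45), hypoxia (-0.69 to -0.41), MHC class I, fibroblast and mesenchymal lists stayed below the 1st. With a filter at the 60th percentile, the counts of genes 2-fold higher and lower became 806 and 891, out of 10930 genes left. That filter takes out dim genes, which were 2-fold different more often. The counts were 3565 and 3407 at 1.5-fold and 575 and 797 at 3-fold. They were 2973 and 3019 over features, and 219 and 201 for genes with 2 or more features that all pass. With no filter the epithelial median was -0.41, now outside the 1st to 99th percentile, and the oncofetal median -0.17, now inside. With the filter at the 60th percentile the epithelial list moved outside (-0.56) and the oncofetal (-0.34) and cholesterol (-0.29) lists inside. With the brightest feature the interferon (-0.32) and MHC class II (-0.80) lists moved inside and the heat shock list outside (0.50), and PHC3 reversed to -0.46. Against unmatched random lists the oncofetal (-0.47), cholesterol (-0.35) and ribosomal protein (-0.20) lists moved inside. With the mean, PRC1 (0.44) and epithelial genes (-0.56) moved outside and interferon genes (-0.29) inside. With only genes of 2 or more features, chemokines and cytokines (0.015) and NF-kB targets (0.063) reversed, the epithelial list moved outside (-0.60) and the oncofetal list inside (-0.34). Named genes that a setting left out, and the leukocyte, neuronal and cancer-testis lists where under 5 members were left, gave no value. The cause of the list changes was not tested. Of the list medians under an alternative, 472 kept their place below, within or above the 1st to 99th percentile. Direction was compared only for lists that stood apart in the main setting. Medians of other lists could change sign, as for HOX genes (-0.07 to 0.31) and endothelial genes (-0.36 to 0.20). Of the values of named genes, 873 moved by less than the SD between features, 44 by more and 1 reversed. Signal over background limits the dimmest genes, and 170 of 333 features with an 8-fold or larger ratio had a value at or below the random probes on their dimmer array.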

Other observations

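Further gene groups were chosen after the data were seen, and ratios are again of the array labelled EZH2 knockdown to wild type. Genes of ribosome biogenesis and other targets of the growth regulator MYC had a median log2 ratio of 0.72 over 30 members (100th percentile of random lists), with 8 members 2-fold or more higher, none lower and 28 above 0. ODC1, the first enzyme of polyamine synthesis, had 1.54, and the nucleolar genes NOP16 and NOP56 had 1.25 (SD 0.43 between 3 features) and 1.19. MYC itself had -0.33 from 1 feature. Genes of homologous recombination and the Fanconi pathway, which repair broken and crosslinked DNA, had a median of 0.60 over 27 members (99.92nd percentile), 9 of them 2-fold or more higher and none lower. FANCD2 had 2.14 and BRIP1 had 1.52 (SD 0.26 between 2 features). Proteasome subunits of the core and the regulatory particle had a median of 0.42 over 31 members (99.99th percentile), 29 of them above 0, with PSMD12 of the regulatory particle at 1.09 (SD 0.21 between 3 features).

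Chromatin assembly genes had a median of 0.39 over 22 members (99.4th percentile). The 2 members shared with the 45 lists, CHAF1A and CHAF1B, belong to the DNA replication list that stood apart. CHAF1A, a histone chaperone of the replication fork, had 1.29 (SD 0.05 between 2 features). ATAD2, which is not in the 45 lists, had 1.28 (SD 0.06 between 2 features). Nucleotide synthesis genes had 0.36 over 23 members (99.2nd percentile), with the pyrimidine enzyme UMPS at 1.17 (SD 0.24 between 2 features). Its members CAD and NME1 were also in the group of ribosome biogenesis and MYC targets. Complement and coagulation genes (-0.46 over 18 members, 5 of them shared with the 45 lists, 1.19th percentile), lysosomal genes (0.03, 3 shared, 43.3rd percentile) and aminoacyl-tRNA synthetases (0.01, 45.8th percentile) did not stand apart, and within the first of these the clotting initiator F3 had 1.91 (SD 0.16 between 3 features) and PLAT, the tissue plasminogen activator, had -1.24 (SD 0.02 between 2 features). The example genes of these lists were picked after their values were seen.

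Tests of the culture state, of single-feature error and of copy number over the whole genome were set before their result was seen, and the other tests were chosen after it. The first pattern is that EZH2 was not lower on the array labelled EZH2 knockdown. Saturation is argued against, since the feature lay at the 76.8th percentile of signal or below on both arrays. A swap of the labels cannot be told apart from the labels as given, because the ratio of -0.054 lies well within 2 SD between features. Whether a lowered EZH2 transcript was masked by the higher level of replication genes, with which EZH2 is known to be co-expressed through E2F, stays open, because that 93.0% of the replication members had a higher ratio than EZH2 follows from the values that prompted the question and holds as well for an unchanged EZH2. A weak knockdown, a feature that misses it or loss at the protein level alone were not tested.

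The second pattern is the higher level of replication genes together with lower hypoxia and glycolysis genes. A trend of the ratio with signal is argued against, since the replication median was still 1.07 after a loess correction. A difference in density or growth state between the cultures may contribute, because quiescence and FOXO target genes were low (-0.60 over 22 members, 0.29th percentile). Of these members 5 were shared with the 45 lists, among them MXI1 of the hypoxia list. But YAP target genes, which sparse culture is known to raise, were low and lay at the 2.66th percentile (-0.21 over 22 members, 6 of them shared). Only 4 YAP members were above 0, and F3 (1.91) was the 1 member 2-fold or more higher. The YAP target ANKRD1, left out of that list, had 3.60 from 1 feature. The lists point different ways, so a difference in culture state stays open. Loss of EZH2 activity stays open too, since polycomb-marked developmental factors lay at the 95.5th percentile and genes reported silenced by EZH2 at the 10.4th. With 1 culture per group, culture and knockdown cannot be told apart for these genes.

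The third pattern is a shift of whole chromosome regions, of which the largest median over 50 neighbouring genes after centring was -0.83 (chromosome 9, first gene at 45242939 and last at 71848316 in HG18), with an absolute size of 0.826 against 0.569 at the 95th percentile of 1000 shuffled gene orders. A copy number difference between the cell populations is a candidate explanation. Families of genes that share probes stay open for this region, where 54% of genes carry LOC names. Thinning dropped all LOC names and then kept 1 gene, picked at random, per letter root of the name and chromosome. The 17 genes left in the region had a median of 0.096 (95% bootstrap interval -1.28 to 0.78). Thinning thus does not separate shared probes from the loss of LOC genes. With only LOC names dropped, the largest shift over the genome was 0.768 in size, above all 1000 shuffled orders (highest 0.655). With the genome thinned in the same way the largest shift was a different one, on chromosome 19 with the first gene at 56526607. It was 0.586 in size and above 987 of 1000 shuffled orders. A window on chromosome 17 was nearly as large (0.583), and these values rest on 1 random pick of the genes kept. On chromosome 17 from 14079897 to 18159440 the median was 0.70, and 26 of the 28 genes left after thinning were above 0 (median 0.86). Elsewhere on chromosome 19, 11 of 11 pregnancy-specific glycoprotein genes, which are close paralogues, were 2-fold or more lower (median -1.79) and 39 other genes of their region had a median of -0.39, and neither shared probes nor base composition was tested on sequences.

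Of 333 features with an 8-fold or larger ratio, 110 had sister features of the same gene that also passed the signal filter. In 50.9% of these the sisters averaged 2-fold or more the same way. The share counts features and not genes. Where several 8-fold features belong to the same gene, each serves as a sister of the other, as for TXNIP (same way) and HHIP (opposite ways). These features are not independent, so the share does not decide whether error of single features lies behind the 8-fold ratios. Sister features that were dim on both arrays were left out, so this share does not cover all sisters on the array.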
